A study of Mus musculus with 4 samples.

How the data were processed

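Single-cell RNA sequencing was done on cells sorted by flow cytometry from mice, in 4 libraries with 1 library per group. Per the labels, the cells were lineage-negative and positive for CD31, VE-cadherin and endomucin, and were split by Sca-1 into a Sca-1-negative gate, called sinusoidal, and a Sca-1-positive gate, called type H after a capillary type of bone. For each gate the labels give a library of Id1 and Id3 knockout mice and a library of control mice, which the sample titles call wild type and the series design text gives as Id1 intact and Id3 heterozygous. Tamoxifen was given on 5 consecutive days to delete Id1, and the design text names a CreER driven by Cdh5 and 20000 sorted cells. The number of mice behind each library and the deleted part of either gene are not given in the sources used here.

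The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, per the file headers and the values, over 27998 genes. Per the labels, cells were captured on the 10x Genomics Chromium and sequenced on an Illumina NextSeq with 26 and 57 cycles. The submitters' processing notes name Cell Ranger, Seurat and the mm10 build, with versions not given in the sources used here, and whether Seurat changed the matrices is not stated. Only called barcodes are in the matrices, so free RNA could not be measured in empty droplets. The Chromium 3' assay reads the ends of transcripts, so a null allele that still makes a transcript can give tags.

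The files held 3641 barcodes. Cells with at least 200 genes and under 10% mitochondrial UMIs were kept, which left out 74 barcodes and kept 3567 cells. The total per library was 3234772 UMIs for the sinusoidal control, 8338220 for the sinusoidal knockout, 5703108 for the type H control and 11065352 for the type H knockout. The sinusoidal library labelled knockout was the deepest per cell, with a median of 15258 UMIs per barcode against 6101.5, 6335 and 5567 in the others. Scrublet, run per library, marked 5, 6, 1 and 3 cells in the same order, and marked cells stayed in the main values. In the type H libraries the marked shares were 0.124% and 0.162%, so doublets were weighed there by cells with both Xist and Y-linked UMIs as well.

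The 4 libraries were clustered together with Python 3.11.15 and scanpy 1.11.5 (10000 UMIs per cell, log1p, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1 with leidenalg 0.10.2). Clusters were named from marker lists of 20 cell classes fixed before the data were examined. The naming rule was set afterwards. A marker counted as detected at 10% of a cluster's cells and as raised at 1.5-fold the mean of the other clusters, with 20 CPM added to both. The class with the highest mean log2 marker level was taken, and its name needed at least 3 and 0.5 of its markers detected, at least 3 raised, no other class with as many raised, and no other class ahead among the 10 leading genes. Ties were set against naming after the clusters had been seen, with no effect on the names of the main clusters. Under the strict filter a cluster of 334 cells, with 6 progenitor and 6 endothelial markers raised, stayed unnamed by a tie. Of 19 clusters 16 were named and 3 stayed unnamed. Of the fixed symbols, 6 had no match in the files.

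No cluster was named endothelial. The planned values over endothelial-like cells therefore could not be given, and the design was kept as written. In their place UMIs were summed over the named classes that make up most of a gate: progenitor-like cells in the type H gate, and granulocyte precursor-like and monocyte-like cells in the sinusoidal gate. This choice was made after the data had been seen. So were 6 further gene lists (stem cell, lymphoid-primed, megakaryocyte-primed, granule protein, monocyte lineage and lymphoid E protein target genes), a split of the cells by Xist and Y-linked UMIs, and an alternative that added unnamed clusters rich in progenitor markers.

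Sums were scaled by their totals to counts in CPM. With 1 library per group no test between a pair of groups was possible. No test of the label over both gates was run, and no p-value was made from cells. A sum has an exact Poisson 95% interval, a share an exact Clopper-Pearson 95% interval, and a ratio of sums an exact 95% interval conditional on the total. These intervals cover counting error only, not the spread between cells, animals or libraries. A log2 ratio was computed with 0.5 UMIs added to each sum. For the 27 gene lists fixed before the data were examined, the value is the median log2 ratio over members with at least 20 UMIs, with an interval from 1000 Poisson redraws and a percentile among 10000 random lists matched in size and expression, which describes these libraries and is not a test. Members at least 1.5-fold higher or lower were counted. The library labelled knockout always stands over the labelled control.

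Genes were named by a rule of size fixed beforehand. Per gate these were up to 12 genes per direction ranked by the bound of the ratio nearest 1, with that bound beyond 1.5-fold and at least 50 CPM in the higher library. Mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes and unnamed gene models were left out, as were genes over 2 times higher in the other cells pooled over the 4 libraries, which are given apart. Other cells of each library alone were compared as well, a choice made after the data had been seen. Id1, Id2, Id3, Id4, Tcf3, Tcf4 and Tcf12 were always reported, with up to 2 members per direction of each list. A further part of the rule asked for genes past the bound in the same direction in both gates.

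Shares of cells with UMIs were compared after thinning each cell to 2000 UMIs. A cell counted as holding G2/M transcripts from 3 UMIs over the G2/M list. Coordinates come from the GENCODE M21 annotation of GRCm38, which is the mm10 build, and are 1-based. The alternatives set beforehand were no cell filter, a strict filter (at least 1000 genes and under 5% mitochondrial UMIs), all cells, the main control clusters (the fewest clusters that hold 50% of the control library's cells of the class), leaving out Scrublet cells, Leiden resolution 2, median-of-ratios scaling, scaling without mitochondrial and ribosomal protein genes, equal weight per cell, and members with at least 100 UMIs. Log2 medians of all genes lay at -0.042, 0.026 and 0.0084 in the progenitor-like, granulocyte precursor-like and monocyte-like comparisons.

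The steps were tested on simulated data with 200 genes changed. The sums were drawn from the Poisson model that the intervals assume. Coverage near 95% was therefore set in advance, and it shows nothing about spread between cells. The interval held the true ratio for 95.5% of 11187 genes in the progenitor-like comparison, 95.7% of 8949 genes in the granulocyte precursor-like comparison and 96.6% of 5161 genes in the monocyte-like comparison. Of genes with at least 50 CPM, the size rule found 96%, 80% and 37% of 2-fold changes and 100%, 100% and 94% of 4-fold changes in the same order. Among unchanged genes of any level, 2, 4 and 4 lay past the 1.5-fold bound. Calculations used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.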

Results

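Single cells from 2 sorted gates of Id1 and Id3 knockout and control mice were compared. Id1 and Id3 are helix-loop-helix proteins that bind E proteins and keep them from DNA, and the series asks what their loss does to the sinusoidal vessels that serve blood formation. The Sca-1-negative sinusoidal gate gave 351 cells from the library labelled control and 553 from the library labelled knockout. The Sca-1-positive type H gate gave 806 and 1857 cells. Each group is 1 library, so no difference has a replicate check, and all intervals are 95% and cover counting error only. The words control and knockout follow the labels. The Id3 values put these in doubt but cannot decide alone, since it is not known whether the null allele still gives tags.

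The sorted cells carried transcripts of blood cells, and nearly none of endothelium. Cdh5, which encodes the VE-cadherin used in the sort, gave 45 UMIs in 28 of 3567 cells, and Kdr, the main VEGF receptor, gave 35 UMIs in 33 cells. Stab2 and Flt4, markers of sinusoidal endothelium, gave 4 UMIs each, Plvap 5 and Ptprb 3. UMIs of at least 2 of these 6 genes occurred in 1 cell, and UMIs of 3 in 0 of 3567 cells, which allows a share of up to 0.0841% of cells with such UMIs and sets no limit on cells that express the genes below detection. UMIs of at least 2 of 8 pan-haematopoietic genes such as Ptprc, Laptm5 and Coro1a occurred in 96.0% of the cells. Ptprc, the CD45 gene, was seen in 71.5%, 61.8%, 44.5% and 39.3% of cells in the sinusoidal control, sinusoidal labelled knockout, type H control and type H labelled-knockout libraries. Free RNA gave wide low shares too: Jchain was seen in 92.8% of cells outside the plasma cell-like cluster of the type H control, at 471 CPM against 191759 CPM in that cluster. No cluster was named endothelial, and the comparisons over endothelial cells that the study's design implies could not be made.

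**Figure D1:**
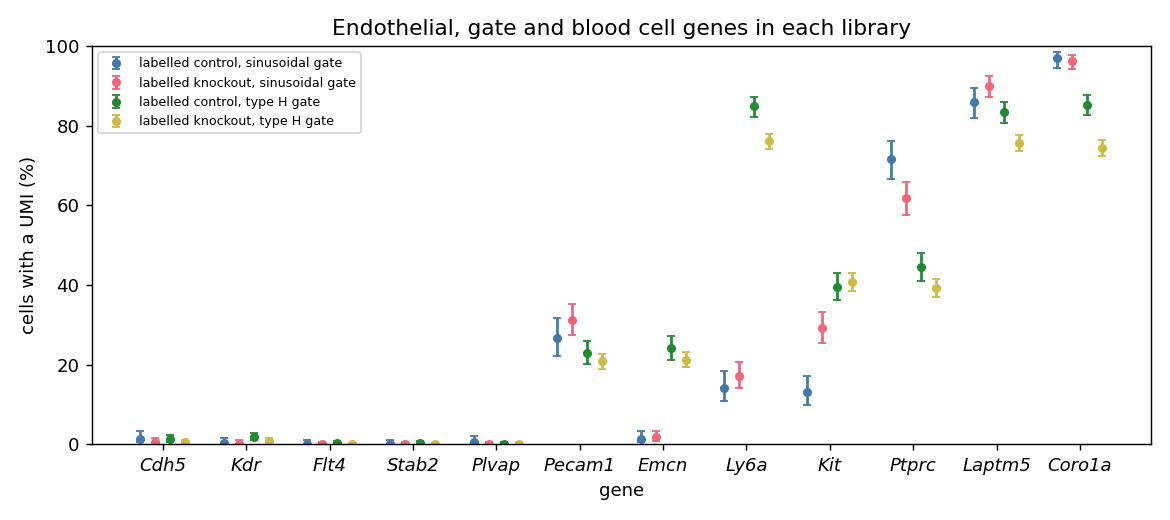
Share of cells with at least 1 UMI of each gene in the 4 libraries, with exact 95% binomial intervals as bars, at unthinned depth. Cdh5, Kdr, Flt4, Stab2 and Plvap lie near 0 in each library, while Ly6a and Emcn separate the type H gate from the sinusoidal gate.

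Other endothelial genes were present in blood progenitors. In the type H gate Emcn, the endomucin gene, stood at 42.4 CPM in the control and 42.7 CPM in the labelled-knockout library, against 1.89 and 1.57 CPM in the sinusoidal gate. Pecam1, the CD31 gene, stood between 31.4 and 44.3 CPM in the 4 libraries. Cluster 4, with 285 cells of the type H gate, scored highest for endothelium but stayed unnamed, because only 7 of 15 endothelial markers were detected in it, and as many progenitor as endothelial markers were raised (6 each). It held Cldn5 in 24.9% of its cells, Hlf in 74.7%, Mecom in 62.1% and Ptprc in 40.0%, and no Cdh5. Under Leiden resolution 2, no cell filter or the strict filter a cluster of 243, 255 or 312 cells made mostly of these cells took the endothelial name by rule, with Cdh5 in 0% of its cells in each setting.

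The gates held different blood cells. Progenitor-like cells made up 66.5% (63.1 to 69.8) of the type H control and 66.3% (64.1 to 68.4) of the type H labelled-knockout library, followed by plasma cell-like cells at 13.5% (11.2 to 16.1) and 8.99% (7.73 to 10.4). The progenitor-like shares were lower in both libraries at Leiden resolution 2, with 43.1% of the control and more of the labelled knockout, and under the strict filter, with more of the control. Under that filter a cluster of 98 control and 234 labelled-knockout cells stayed unnamed by a tie of progenitor and endothelial markers. The sinusoidal control held 43.9% (38.6 to 49.2) monocyte-like and 25.9% (21.4 to 30.8) granulocyte precursor-like cells. The sinusoidal labelled knockout held 10.7% (8.22 to 13.5) and 46.1% (41.9 to 50.4) of these classes. Under the strict filter the monocyte-like shares were 39.3% of the control and 21.7% of the labelled knockout. There the class took in a cluster led by F13a1, with 15 control and 59 labelled-knockout cells. A cluster of 41 control and 6 labelled-knockout cells of this gate stayed unnamed there. Its leading genes included Ear2, Fcgr4 and Gngt2, which lead monocyte-like cluster 12 of the main clusters, beside T cell genes such as Cd3g. The change in shares is thus in part one of naming. Unnamed cluster 8, with the monocyte genes F13a1, Ly6c2 and Ms4a6c among its leading genes, held 20 of 351 and 159 of 553 cells of the same libraries. The unnamed clusters 4, 7 and 8 took 8.83%, 33.8%, 12.8% and 18.5% of the sinusoidal control, sinusoidal labelled knockout, type H control and type H labelled-knockout libraries. Erythroid-like cells were 4.27% and 1.99% of the sinusoidal control and labelled knockout, basophil and mast cell-like cells 4.56% and 4.88%, T and NK-like cells 5.13% and 0.542%, dendritic cell-like cells 3.99% and 0.723%, and B lymphoid-like cells 2.28% and 0.181%. What set these shares was not tested. The cells were sorted, and the sinusoidal control and labelled knockout differ in depth, with medians of 6142 and 15428 UMIs per cell. Within classes these medians lay closer, at 15572 and 16437 in granulocyte precursor-like and 5283.5 and 5766 in monocyte-like cells. The library medians thus differ at least in part with the cells held.

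**Figure D2:**
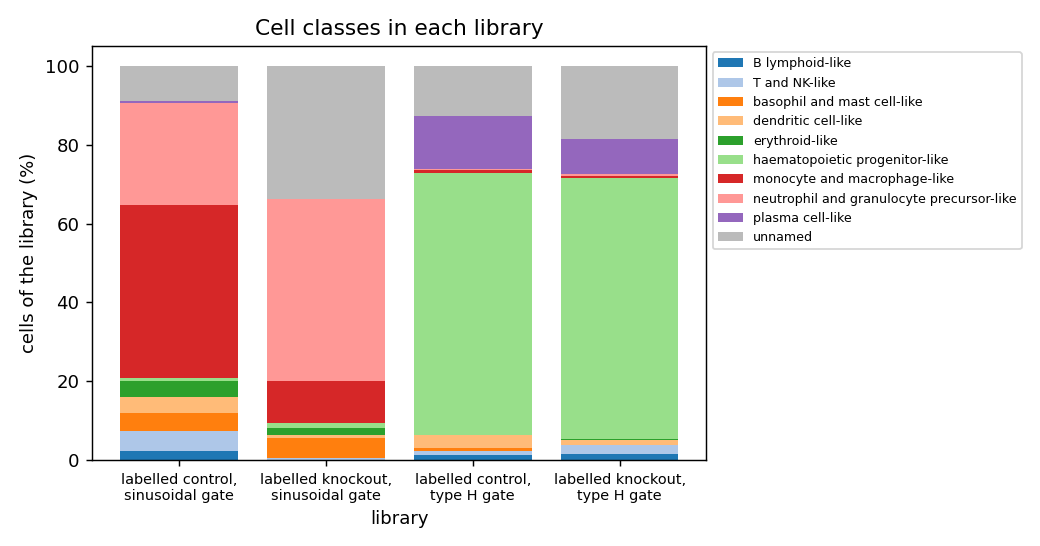
Share of cells of each library, in percent, by cell class named from fixed markers, with unnamed clusters in grey. Progenitor-like cells fill 66.5% and 66.3% of the type H libraries, while monocyte-like cells fill 43.9% of the sinusoidal control and 10.7% of the sinusoidal library labelled knockout, or 39.3% and 21.7% under the strict filter, where the clusters given that name differ.

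The targeted genes were examined first, as a check of the labels. Id3 (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755, GRCm38) was higher in the libraries labelled knockout. In progenitor-like cells of the type H gate it stood at 88.7 CPM (81.7 to 96.3) against 34.2 CPM (28.4 to 40.9) in the control, a ratio of 2.59 (2.13 to 3.18). The ratio was 1.83 (1.22 to 2.81) in granulocyte precursor-like cells, at 36.1 against 19.8 CPM, and 3.41 (2.62 to 4.45) in monocyte-like cells, at 431 against 127 CPM. Over all cells Id3 stood at 84.9 against 33.0 CPM in the type H gate and at 84.8 against 54.7 CPM in the sinusoidal gate. Among clusters with enough cells Id3 was higher in the library labelled knockout in 9 of 10 in the type H gate, with the interval above 1 in 8. In the sinusoidal gate it was higher in 4 of 6, with the interval above 1 in 2, while cluster 10 had a ratio of 0.843 (0.411 to 1.83) and the erythroid-like cluster held no Id3 UMI in either library.

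Id1 (ENSMUSG00000042745, chromosome 2, 152736251 to 152737410) was too low in progenitor-like and monocyte-like cells to check the labels there. Over all cells of the sinusoidal gate it stood at 26.3 against 26.1 CPM, a ratio of 1.01 (0.779 to 1.31) from 218 and 83 UMIs. Over the type H gate it stood at 2.99 against 4.08 CPM (0.734, 0.418 to 1.31), from 33 and 23 UMIs. Progenitor-like cells held 9 Id1 UMIs in the labelled-knockout and 8 in the control library, a ratio of 0.603 (0.207 to 1.80). In granulocyte precursor-like cells the ratio was 0.719 (0.439 to 1.21), from 53 and 25 UMIs, an interval that leaves out a near-complete loss of tags, and in monocyte-like cells 0.303 (0.0336 to 1.30), from 2 and 15 UMIs. As log2 the last ratio was -1.45, and it turned to 1.52 under the strict filter, where the class took in other cells. The deletion was directed to cells that use Cdh5, so blood cells need not carry it. Tags from outside the deleted part of either gene would check nothing, and that part is not given in the sources used here.

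After thinning to 2000 UMIs, Id3 was seen in 17.3% (15.2 to 19.6) of progenitor-like cells of the labelled knockout and 6.06% (4.18 to 8.45) of the control library, against 34.0% and 17.9% unthinned. Thinned shares were 9.02% and 2.20% in granulocyte precursor-like cells and 61.0% and 18.8% in monocyte-like cells, against 40% and 23.1%, and 86.4% and 37.7%, unthinned. As a gauge of free RNA, the erythroid-like cells of the sinusoidal gate held 0 Id3 UMIs. With 11 labelled-knockout and 15 control cells, this is too few to exclude free Id3 RNA. Id1 was seen in 0.172% and 0.189% of thinned progenitor-like cells, in 3.14% and 3.30% of granulocyte precursor-like cells and in 0 of 59 and 3.25% of monocyte-like cells.

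In progenitor-like cells the ratios of the E protein genes were 0.906 (0.783 to 1.05) for Tcf3, 0.915 (0.796 to 1.05) for Tcf4 and 1.17 (0.95 to 1.44) for Tcf12, and Id2 was at 1.19 (0.816 to 1.75). Tcf3 had a ratio of 1.34 (0.992 to 1.83) in granulocyte precursor-like cells, and Tcf4 one of 0.592 (0.487 to 0.721) over all cells of the sinusoidal gate. Within its classes Tcf4 was at 0.854 (0.548 to 1.36) in granulocyte precursor-like and 1.45 (0.795 to 2.58) in monocyte-like cells. Granulocyte precursor-like cells of the labelled-knockout library held less Id2, at 55.0 against 79.0 CPM and a ratio of 0.696 (0.555 to 0.877). Monocyte-like cells held more, at 390 against 238 CPM and a ratio of 1.64 (1.30 to 2.06). Id4 gave at most 2 UMIs in any library. The list of Id and E protein genes had medians of 0.22 in progenitor-like cells, -0.070 in granulocyte precursor-like and 0.54 in monocyte-like cells.

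Id3 levels also split by sex-linked transcripts, since each library held cells with Xist and cells with Y-linked UMIs. In the type H control Id3 stood at 4.34 CPM (1.41 to 10.1) in 170 cells with Xist and no Y-linked UMI, against 38.8 CPM (32.2 to 46.3) in 423 cells with a Y-linked UMI and no Xist. In the sinusoidal control these values were 6.39 CPM (1.74 to 16.4) and 52.6 CPM (42.2 to 64.8), in 62 and 163 cells. The libraries labelled knockout showed 81.2 against 85.6 CPM in the type H gate and 94.7 against 74.4 CPM in the sinusoidal gate. This split was chosen after the data had been seen. Cells with both kinds of transcript were 2.56%, 2.53%, 2.23% and 1.51% of the sinusoidal control, sinusoidal labelled knockout, type H control and type H labelled knockout.

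**Figure D3:**
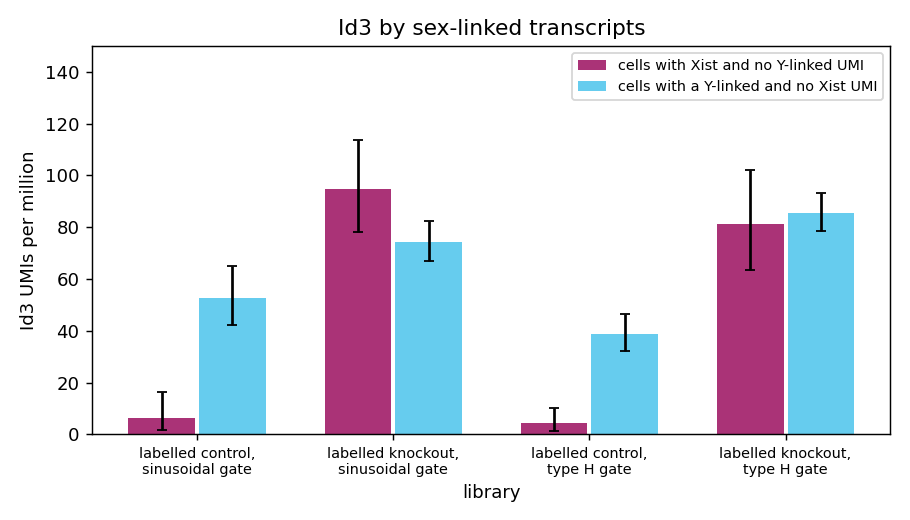
Id3 CPM in cells with Xist and no Y-linked UMI and in cells with a Y-linked UMI and no Xist, in each library, with exact 95% Poisson intervals as error bars. Id3 is at 4.34 and 6.39 in the Xist cells of the libraries labelled control and between 38.8 and 94.7 elsewhere.

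Progenitor-like cells of the type H gate were compared between 1231 cells of the library labelled knockout and 536 of the control. The direction is taken from labels that Id3 puts in doubt. Several immediate-early genes were higher in the library labelled knockout. Jund, an AP-1 subunit, stood at 956 against 458 CPM (ratio 2.09, 1.97 to 2.20), Jun at 532 against 327 CPM (1.63, 1.52 to 1.74) and Nr4a1, an orphan nuclear receptor, at 236 against 133 CPM (1.78, 1.61 to 1.98). Of 16 measured immediate-early and heat shock genes 6 were at least 1.5-fold higher and 0 lower, and the median log2 ratio was 0.41 (0.35 to 0.47), at the 100 percentile of random lists. Hsp90aa1 and Hspa8 had ratios of 0.782 and 0.950. In the main control clusters 0 and 3 the median was 0.15.

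The largest ratio by the size rule was that of Cebpb, a transcription factor of myeloid cells, at 126 against 29.1 CPM (4.34, 3.53 to 5.38). Kdm6b, a histone H3 lysine demethylase, had a ratio of 2.28 (1.85 to 2.83) and Notch2 2.04 (1.67 to 2.52). In the same direction the class I gene H2-Q4 stood at 155 against 79.0 CPM, Klf2 at 350 against 191 CPM, Spag7 had a ratio of 1.92 (1.53 to 2.41), the sphingosine phosphate transporter Spns2 1.83 (1.58 to 2.13) and the kinase Sik1 1.77 (1.51 to 2.08). Serinc3 was the gene named as lower, at 300 against 591 CPM (0.508, 0.477 to 0.541). Notch2 and Kdm6b are among the leading genes of cluster 1, which held 21.0% of the cells of the type H labelled knockout and 7.57% of the type H control library. Cluster 1 was the shallowest progenitor-like cluster, with a median of 3129.5 UMIs per cell against 5544.5 to 6332 in clusters 0, 2 and 3. The other cells of the type H labelled knockout held over 2 times more Jund, Jun and Klf2, at 1932, 2013 and 934 CPM. In clusters 0 and 3 alone the log2 ratio of Notch2 was 0.39 in place of 1.03 and that of Kdm6b 0.88 in place of 1.18.

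Notch pathway genes, with 8 measured, had a median log2 ratio of 0.51 (0.079 to 0.86), at the 99.9 percentile. Of these 4 were at least 1.5-fold higher, among them Notch2 and the Notch target Hes1, with a ratio of 1.81 (1.28 to 2.62). Cell cycle inhibitors had a median of 0.11 (-0.01 to 0.24), with the antiproliferative gene Btg2 at 246 against 156 CPM (1.57, 1.42 to 1.73) and Cdkn1a at a ratio of 1.26. G2/M genes had a median of 0.31 (0.081 to 0.59) over 11 measured members of low level, and -0.15 with the unnamed progenitor clusters added, while S phase genes lay at -0.077. The share of thinned cells with G2/M transcripts was 0.429% (0.139 to 0.999) in the labelled-knockout and 0.758% (0.207 to 1.93) in the control library, against 5.52% and 4.48% unthinned. The class leaves out unnamed cluster 7, with Cenpf, Ccnb2, Cdc20 and Top2a among its leading genes and 114 labelled-knockout and 43 control cells of this gate. Thinning left out 66 and 8 cells.

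Pro-apoptotic genes had a median of -0.15 (-0.25 to -0.056), at the 4.67 percentile, with 0 of 17 members 1.5-fold higher or lower, and anti-apoptotic genes 0.062 (-0.013 to 0.21). Bcl2l1, an inhibitor of apoptosis, had a ratio of 1.47 (1.06 to 2.05). p53 target genes lay at -0.15, interferon response genes at -0.040, MHC genes at 0.0092, inflammatory NF-kB genes at -0.046, unfolded protein response genes at -0.11, hypoxia and glycolysis genes at -0.14, oxidative phosphorylation genes at -0.11 and scavenging and lysosome genes at -0.16. The BMP and TGF-beta pathway lay at -0.13, with Skil, a repressor of SMAD proteins, at a ratio of 1.81 (1.46 to 2.26). Lists named for endothelium rested on few members that blood cells use, with medians of -0.26 for sinusoidal, -0.034 for arteriolar, -0.065 for type H associated, 0.021 for angiogenic receptor, 0.062 for anti-angiogenic, -0.026 for junction, -0.078 for mesenchymal transition, -0.19 for basement membrane and -0.057 for niche factor genes. The sex-linked list lay at -0.0098, with Xist at 161 against 407 CPM.

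Of the lists chosen after cell types were seen, stem cell genes had a median of -0.15 (-0.22 to -0.088), with Mycn at a ratio of 0.628 and Gata2 at 1.15. Megakaryocyte-primed genes lay at -0.20, lymphoid-primed genes at -0.073, monocyte lineage genes at 0.064, lymphoid E protein target genes at 0.17 and granule protein genes at 0.28. The last list includes Camp and Elane, which reached only 10.2 and 4.44 CPM in the library labelled knockout, from 67 and 29 UMIs.

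Granulocyte precursor-like cells of the sinusoidal gate were compared between 255 cells of the library labelled knockout and 91 of the control, again by labels that Id3 puts in doubt. Some genes of later neutrophils were lower in the library labelled knockout. Lactoferrin (Ltf) stood at 160 against 1250 CPM (ratio 0.128, 0.117 to 0.140), Lcn2, an iron-siderophore binding protein, at 254 against 1771 CPM (0.144, 0.134 to 0.154), and Ly6g, a surface antigen of neutrophils, at 7.40 against 69.5 CPM (0.106, 0.0692 to 0.160). Elane, made in early precursors, was at 19792 against 16132 CPM (1.23, 1.21 to 1.24). Ncmap was the gene named as higher, at 52.7 against 16.4 CPM (3.22, 2.11 to 5.14).

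The genes named as lower also included Ifitm6 (0.0707, 0.0592 to 0.0841), Chil1 (0.181), Cd177 (0.321), Retnlg (0.324), Polr2l (0.390), Anxa1 (0.422) and S100a9 (0.475). Cd74, Serinc3, Ctss, Ccl3 and Lgals3 were lower as well but were set aside because other cells held over 2 times more. The same holds for Lyz2 (0.380) and S100a6 (0.246) by the other cells of the sinusoidal control alone, which held 22747 CPM of Lyz2 and 1562 CPM of S100a6 against 3750 and 183 CPM in the class. Several of these genes mark cluster 10, the later precursors, which held 26 of 91 control and 52 of 255 labelled-knockout cells of the class. In cluster 6, the main control cluster, most of these log2 ratios were nearer 0: Ifitm6 (-0.68 in place of -3.82), Lcn2 (-0.44 in place of -2.80), S100a9 (-0.14 in place of -1.07), Ly6g (-1.60 in place of -3.22), Chil1 (-1.16 in place of -2.46), S100a6 (-0.29 in place of -2.02), Anxa1 (-0.31 in place of -1.25), Lyz2 (-0.47 in place of -1.39) and Cd177 (-0.95 in place of -1.64). They were -2.96 for Ltf, -2.52 for Retnlg and -1.47 for Polr2l. Ratios of these genes within cluster 10 are not given here, so its share of cells is not shown to account for the differences. The rule for both gates named no gene. Serinc3 was past the bound and lower in both, but in these cells, at 91.1 against 177 CPM (0.514, 0.439 to 0.604), it was set aside for the 443 CPM of the pooled other cells.

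The hypoxia and glycolysis list of these cells had a median of -0.24 (-0.42 to -0.061), at the 0.67 percentile, with 4 of 14 members at least 1.5-fold lower and 0 higher, but with members of at least 100 UMIs the median was -0.044. Its glycolytic enzymes Pgk1 and Eno1 had ratios of 0.420 (0.280 to 0.634) and 0.684 (0.628 to 0.745), while Ldha was at 1.11. Oxidative phosphorylation genes had a median of 0.16 (0.11 to 0.21), at the 95.2 percentile. Cell cycle inhibitors had a median of -0.27 (-0.43 to 0.016), with Cdkn1b at a ratio of 0.403, and 0.017 in cluster 6 alone. Unfolded protein response genes lay at -0.095 and S phase genes at 0.14. The G2/M share of thinned cells was 36.9% (30.9 to 43.1) in the labelled-knockout and 35.2% (25.4 to 45.9) in the control library, against 91.4% and 81.3% unthinned.

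The remaining fixed lists with at least 5 measured members had medians between -0.18, for p53 target genes, and 0.14, for interferon response genes. Among lists chosen after cell types were seen, monocyte lineage genes had a median of -0.66 (-0.90 to -0.22), with 7 of 13 members at least 1.5-fold lower, and granule protein genes -0.12, with 6 of 15 lower, 0.012 in Y cells and 0.056 over all cells. Stem cell genes lay at -0.38, lymphoid-primed genes at -0.13, megakaryocyte-primed genes at -0.40 and lymphoid E protein target genes at -0.33. Cx3cr1, a chemokine receptor of monocytes, had a ratio of 0.271 (0.132 to 0.551). The control library held more monocyte-like cells, 43.9% against 10.7%, or 39.3% against 21.7% under the strict filter, and Lyz2 was seen in 98.5% and 92.5% of its and the labelled-knockout library's other cells. These other cells include clusters 8 and 10, at 6840 and 6796 CPM of Lyz2, so the shares cannot tell free RNA from transcripts of the cells.

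In monocyte-like cells of the sinusoidal gate, 59 in the library labelled knockout and 154 in the control, most interferon response genes were lower in the library labelled knockout. The median log2 ratio was -2.0 (-2.52 to -1.53), at the 0 percentile of random lists, and 14 of 19 measured members were at least 1.5-fold lower and 0 higher. Ifit3 and Ifit1, which encode antiviral proteins, had 0 UMIs in the labelled-knockout library against 89.1 and 62.0 CPM in the control, at least 10.1-fold and 7.04-fold lower against a floor of 3 counts in that library. The exact intervals allow folds as small as 8.01 and 5.51. Isg15, a ubiquitin-like modifier, stood at 23.5 against 212 CPM (ratio 0.111, 0.0471 to 0.224) and Oasl2 at 20.5 against 106 CPM (0.194, 0.0756 to 0.418). The abundant member Ifi27l2a went the other way, at 2048 against 1755 CPM. Summed over the list, UMIs stood at 7374 against 8958 CPM, with medians of 40 and 37 UMIs per cell. At Leiden resolution 2 a monocyte-like cluster of 11 cells, with Ifi204, Ifit3, Isg15 and Ifit2 among its leading genes, came from the control library alone. How much of the difference these cells carry was not measured, so the median need not describe a shift of the whole class. With genes at 0 UMIs set to the floor of 3 counts, and 0.5 UMIs added to none, the median was -2.14, with members of at least 100 UMIs -1.08, and in cluster 9 alone -2.10.

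MHC genes of the monocyte-like cells had a median of -0.25 (-0.31 to 0.071), with the class I genes H2-D1 and H2-K1 at ratios of 0.730 (0.672 to 0.793) and 0.679 (0.576 to 0.798). Anti-apoptotic genes had a median of -0.36 (-0.95 to -0.13), with Bcl2a1b at a ratio of 0.224 (0.0790 to 0.515). Oxidative phosphorylation genes lay at 0.18 (0.063 to 0.25) and G2/M genes at -0.50 (-1.35 to -0.16), over 8 members of few UMIs, which turned to 0.16 with equal weight per cell. Ier3, an immediate-early gene, had a ratio of 3.51 (2.49 to 4.99), while its list lay at 0.052. The other fixed lists with at least 5 measured members lay between -0.19, for cell cycle inhibitors, and 0.30, for mesenchymal transition genes. Among the lists chosen later, granule protein genes lay at -0.21, lymphoid-primed genes at -0.11 and monocyte lineage genes at 0.082, and the others had at most 2 measured members. Thinned cells with G2/M transcripts were 3.39% (0.413 to 11.7) of the labelled-knockout and 1.95% (0.404 to 5.59) of the control library, against 10.2% and 3.25% unthinned. Cluster 9 held 54 of 59 labelled-knockout and 110 of 154 control cells of the class, and cluster 12 the rest.

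The gates were compared within each label over all cells. Ly6a, which encodes Sca-1 and was used to choose the cells, was 24.7-fold (20.5 to 30.2) higher in the type H gate of the control and 44.0-fold (37.1 to 52.7) higher in that of the labelled knockout, which is no finding. The stem cell genes Hlf and Procr were 47.2-fold (29.7 to 79.8) and 77.6-fold (33.1 to 240) higher in the type H control, and the granule gene Mpo had a ratio of 0.00941 (0.00795 to 0.0111). As log2 of sinusoidal over type H, S phase genes had medians of 1.02 and 1.63 in the control and labelled knockout and G2/M genes 0.60 and 1.51. MHC genes lay at -0.71 and -1.72, interferon response genes at -0.44 and -1.90, arteriolar genes at -2.23 and -3.82, sinusoidal endothelial genes at 0.11 and 0.20, and type H associated genes at -0.31 and -0.41. Under median-of-ratios scaling the type H associated medians were 0.052 and 0.011, while in the main control clusters both lay further from 0, with -2.43 in the labelled knockout. With members of at least 100 UMIs that of the control lay nearer 0 and that of the labelled knockout further from it. In the main control clusters the G2/M medians were 3.90 and 4.26. Without a cell filter the sinusoidal endothelial medians were 0.053 and -0.58. The gates hold different blood cells, so these values need not be differences within a cell type.

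The label difference in the type H gate was set against that in the sinusoidal gate, in progenitor-like and granulocyte precursor-like cells. Id3 differed by 0.52 (-0.18 to 1.12) on the log2 scale, Id1 by -0.25 (-1.84 to 1.33) and Id2 by 0.76 (0.17 to 1.39), type H minus sinusoidal. Across 2973 genes with at least 200 UMIs, the log2 ratios had Pearson's r of -0.041 and Spearman's rho of -0.058, where genes are not independent replicates. The classes compared are different cell types, so the gate and the cell type cannot be told apart.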

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

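The gene lists were fixed before the data were examined, but the cell classes they were summed over, and so these differences, were chosen after it. Oxidative phosphorylation genes had a median log2 ratio above 0 in granulocyte precursor-like cells, at 0.16, and in monocyte-like cells, at 0.18, both of the sinusoidal gate. Their median lay below 0 in progenitor-like cells of the type H gate, at -0.11. In each of these classes 0 of 18 members were 1.5-fold higher or lower. G2/M genes were lower in monocyte-like cells, at -0.50, and higher in progenitor-like cells, at 0.31. In each case a label difference went in opposite directions in different cell types, with counting intervals that exclude 0. The oxidative phosphorylation medians lay within the range of 95% of random lists, at the 95.2, 97.1 and 7.89 percentiles, and so did the G2/M medians, at the 4.27 percentile in monocyte-like and just inside the upper end in progenitor-like cells. The G2/M median of monocyte-like cells turned to 0.16 with equal weight per cell and to 1.68 under the strict filter, where the class took in other cells. That of progenitor-like cells turned to -0.15 with unnamed progenitor clusters added and to 0.025 over all cells. The differences between cell types were not tested, since each group is 1 library.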

How the results depend on the processing

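Chosen after the data were seen were the class sums, the 6 added lists, the Xist and Y-cell splits, the addition of unnamed progenitor clusters, and which gate comparison lists answer that comparison. Of the alternative values for results that answer a comparison, 800 stayed within the counting interval of the main value and 166 moved outside it, some of them across 0 from a main value that was not set apart from 0, where a gene counts as set apart by its interval and a list by lying in the outer 5% of random lists. A further 2 changed sign from a main value that was set apart. For the other results these numbers were 443, 141 and 9. Cell cycle inhibitors of granulocyte precursor-like cells changed sign in this way in the main control clusters, and their unfolded protein response genes did over all cells. Id3 stayed higher in the library labelled knockout in each class and setting run, and the monocyte-like interferon median stayed below -1. No paired analysis was possible because each group is 1 library and the labels give no shared replicate numbers. The endothelial cell values fixed beforehand could not be given. Lists with fewer than 5 measured members, the Id and E protein list and the sex-linked list were not recomputed under the alternatives, and Xist-cell values of monocyte-like cells, 6 in the labelled knockout, are not counted above; there Id3 had a ratio of 31.5 (4.66 to 1347) and 20 of 24 named genes kept their direction (17 of 24 over all cells). All cells means the whole gate, so both sinusoidal classes share its values, counted for each. These and resolution 2 have no gate comparison value. Depth limits G2/M and endothelial genes, and Id1 within the classes, which rest on few UMIs. Values below are log2 except percents, and no cause was tested.

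Granulocyte precursor-like values without Scrublet cells went from 0.13 to 0.33 for mesenchymal transition genes.

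Progenitor-like values in Xist cells went from 1.37 to 4.35 for Id3, from 0.11 to 0.39 for cell cycle inhibitors, from -0.077 to -0.80 for S phase genes and from 0.31 to 0.072 for G2/M genes median log2, progenitor-like, type H gate. Others went from -0.15 to -0.29 for pro-apoptotic genes, from -0.26 to -0.67 for sinusoidal endothelial genes, from -0.065 to 0.16 for type H associated genes and from -0.13 to 0.25 for BMP and TGF-beta pathway genes. Others went from -0.026 to 0.17 for junction and adhesion genes, from -0.040 to -0.36 for interferon response genes, from -0.046 to 0.35 for inflammatory NF-kB genes and from 0.0092 to -0.40 for MHC genes. Others went from 0.41 to 0.89 for immediate-early and heat shock genes, from -0.11 to -0.16 for oxidative phosphorylation genes and from -0.16 to -0.30 for scavenging and lysosome genes. Granulocyte precursor-like values in Xist cells went from 0.85 to 2.58 for Id3, from 0.14 to -0.17 for S phase genes, from 0.019 to -0.12 for G2/M genes and from 0.032 to -0.40 for pro-apoptotic genes. Others went from -0.16 to 0.67 for anti-apoptotic genes, from 0.14 to -0.070 for interferon response genes, from -0.067 to -0.31 for inflammatory NF-kB genes and from 0.13 to -0.14 for MHC genes. Others went from -0.022 to 0.23 for immediate-early and heat shock genes, from -0.095 to -0.54 for unfolded protein response genes, from -0.24 to -0.43 for hypoxia and glycolysis genes and from 0.16 to -0.0034 for oxidative phosphorylation genes median log2, granulocyte precursor-like, sinusoidal gate. The gate difference in Xist cells went from 0.52 to 1.77 for Id3.

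Progenitor-like values in Y cells went from 0.0092 to 0.16 for MHC genes. Granulocyte precursor-like values in Y cells went from 0.019 to -0.14 for G2/M genes, from 0.14 to 0.64 for interferon response genes, from 0.13 to 0.26 for MHC genes and from -0.12 to 0.012 for granule protein genes. Monocyte-like values in Y cells went from 0.039 to 0.93 for S phase genes, from -0.50 to -1.82 for G2/M genes median log2, monocyte-like, sinusoidal gate, from -0.038 to 0.60 for p53 target genes and from -0.011 to 0.27 for pro-apoptotic genes. Others went from -2.00 to -2.54 for interferon response genes, from -0.25 to -0.48 for MHC genes, from 0.052 to 0.30 for immediate-early and heat shock genes and from 0.18 to 0.050 for oxidative phosphorylation genes.

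From progenitor-like to all cells, G2/M genes went from 0.31 to 0.025 and mesenchymal transition genes from -0.078 to 0.12. MHC genes went from 0.0092 to -0.028 and granule protein genes from 0.28 to -0.21. From granulocyte precursor-like to all cells, S phase genes went from 0.14 to 0.59 and G2/M genes from 0.019 to 0.63. Pro-apoptotic genes went from 0.032 to -0.12 and p53 target genes from -0.18 to -0.46. Others went from -0.16 to -0.34 for anti-apoptotic genes, from 0.068 to -0.30 for BMP and TGF-beta pathway genes, from 0.13 to -0.73 for mesenchymal transition genes and from 0.14 to -1.87 for interferon response genes. Others went from -0.067 to -0.90 for inflammatory NF-kB genes, from 0.13 to -0.66 for MHC genes, from -0.022 to -0.63 for immediate-early and heat shock genes and from -0.095 to 0.0027 for unfolded protein response genes. Others went from 0.16 to 0.28 for oxidative phosphorylation genes, from -0.061 to -0.80 for scavenging and lysosome genes and from -0.12 to 0.056 for granule protein genes. From monocyte-like to all cells, Id3 went from 1.77 to 0.63 and G2/M genes from -0.50 to 0.63. Mesenchymal transition genes went from 0.30 to -0.73 and p53 target genes from -0.038 to -0.46. Others went from 0.14 to -0.90 for inflammatory NF-kB genes, from -0.25 to -0.66 for MHC genes, from 0.052 to -0.63 for immediate-early and heat shock genes and from 0.11 to -0.20 for hypoxia and glycolysis genes. Others went from 0.18 to 0.28 for oxidative phosphorylation genes and from 0.048 to -0.80 for scavenging and lysosome genes.

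Percents of cells with G2/M transcripts from 2 UMIs per cell went from 0.429 to 3.0 for labelled knockout type H, from 0.758 to 3.03 for control type H, from 36.9 to 49.4 for labelled knockout sinusoidal and from 35.2 to 49.5 for control sinusoidal.

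Progenitor-like values with equal weight per cell went from 0.0092 to -0.038 for MHC genes. Granulocyte precursor-like values with equal weight per cell went from 0.16 to 0.22 for oxidative phosphorylation genes. Monocyte-like values with equal weight per cell went from -0.50 to 0.16 for G2/M genes, from 0.30 to 0.53 for mesenchymal transition genes and from -0.25 to -0.31 for MHC genes. With equal weight per cell, sinusoidal over type H values in the control went from 1.02 to 0.88 for S phase genes, from 0.60 to 0.73 for G2/M genes, from -0.71 to -0.41 for MHC genes and from -0.63 to 0.037 for immediate-early and heat shock genes. With equal weight per cell, sinusoidal over type H values in the labelled knockout went from 1.63 to 1.84 for S phase genes, from 1.51 to 2.12 for G2/M genes and from -1.72 to -1.58 for MHC genes.

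Progenitor-like values in the main control clusters went from -0.034 to 0.21 for arteriolar endothelial genes, from -0.040 to 0.037 for interferon response genes, from 0.0092 to 0.13 for MHC genes and from 0.41 to 0.15 for immediate-early and heat shock genes. Granulocyte precursor-like values in the main control clusters went from -0.27 to 0.017 for cell cycle inhibitors, from 0.14 to 0.014 for S phase genes and from 0.16 to 0.10 for oxidative phosphorylation genes. In the main control clusters, sinusoidal over type H values in the control went from -4.62 to -3.93 for Ly6a log2 ratio sinusoidal gate over type H gate, control, from 1.02 to 1.37 for S phase genes, from 0.60 to 3.90 for G2/M genes and from 0.95 to -0.64 for angiogenic receptors and tip cell genes. Others went from -2.23 to -2.94 for arteriolar endothelial genes median log2 sinusoidal gate over type H gate, control, from -0.31 to -1.81 for type H associated genes median log2 sinusoidal gate over type H gate, control, from -0.69 to 0.97 for unfolded protein response genes and from 0.21 to -3.72 for megakaryocyte-primed progenitor genes median log2 sinusoidal gate over type H gate, control. In the main control clusters, sinusoidal over type H values in the labelled knockout went from 1.63 to 1.97 for S phase genes, from 1.51 to 4.26 for G2/M genes, from 0.20 to 1.17 for sinusoidal endothelial genes and from -0.41 to -2.43 for type H associated genes. Others went from -1.90 to -2.34 for interferon response genes median log2 sinusoidal gate over type H gate, labelled knockout, from -1.72 to -1.53 for MHC genes and from -0.71 to 1.35 for unfolded protein response genes.

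With median-of-ratios scaling, sinusoidal over type H values in the control went from -4.62 to -4.26 for Ly6a log2 ratio sinusoidal gate over type H gate, control, from 1.02 to 1.38 for S phase genes, from 0.60 to 0.97 for G2/M genes and from -0.31 to 0.052 for type H associated genes. Others went from -0.44 to -0.080 for interferon response genes and from -0.71 to -0.34 for MHC genes. With median-of-ratios scaling, sinusoidal over type H values in the labelled knockout went from -5.45 to -5.03 for Ly6a log2 ratio sinusoidal gate over type H gate, labelled knockout, from 1.63 to 2.06 for S phase genes, from 1.51 to 1.93 for G2/M genes and from 0.20 to 0.62 for sinusoidal endothelial genes. Others went from -0.41 to 0.011 for type H associated genes, from -1.90 to -1.48 for interferon response genes and from -1.72 to -1.30 for MHC genes.

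Granulocyte precursor-like values over members with at least 100 UMIs went from 0.068 to 0.94 for BMP and TGF-beta pathway genes, from 0.13 to 0.20 for MHC genes and from -0.24 to -0.044 for hypoxia and glycolysis genes. Monocyte-like values over members with at least 100 UMIs went from -2.00 to -1.08 for interferon response genes. Over members with at least 100 UMIs, sinusoidal over type H values in the control went from -2.23 to -2.84 for arteriolar endothelial genes median log2 sinusoidal gate over type H gate, control and from -3.03 to 1.09 for basement membrane genes. Over members with at least 100 UMIs, sinusoidal over type H values in the labelled knockout went from -0.41 to -3.54 for type H associated genes median log2 sinusoidal gate over type H gate, labelled knockout.

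Granulocyte precursor-like values without a cell filter went from -0.094 to -0.66 for angiogenic receptors and tip cell genes and from -0.095 to -0.27 for unfolded protein response genes. Percents of cells without a cell filter went from 25.9 to 20.4 for granulocyte precursor-like in the control sinusoidal and from 46.1 to 31.7 for granulocyte precursor-like in the labelled knockout sinusoidal. Without a cell filter, sinusoidal over type H values in the labelled knockout went from 0.20 to -0.58 for sinusoidal endothelial genes.

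Percents of cells with G2/M transcripts without thinning went from 0.429 to 5.52 for labelled knockout type H, from 0.758 to 4.48 for control type H, from 36.9 to 91.4 for labelled knockout sinusoidal and from 35.2 to 81.3 for control sinusoidal.

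Progenitor-like values at Leiden resolution 2 went from -0.077 to -0.28 for S phase genes and from -0.14 to -0.21 for hypoxia and glycolysis genes. Granulocyte precursor-like values at Leiden resolution 2 went from 0.13 to 0.25 for MHC genes and from -0.095 to -0.18 for unfolded protein response genes. Percents of cells at Leiden resolution 2 went from 66.5 to 43.1 for progenitor-like in the control type H, from 66.3 to 48.9 for percent of cells haematopoietic progenitor-like, knockout type H gate and from 46.1 to 37.4 for granulocyte precursor-like in the labelled knockout sinusoidal.

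Progenitor-like values with the strict filter went from -0.077 to 0.075 for S phase genes, from -0.040 to 0.049 for interferon response genes median log2, progenitor-like, type H gate and from 0.41 to 0.26 for immediate-early and heat shock genes. Granulocyte precursor-like values with the strict filter went from 0.068 to 0.63 for BMP and TGF-beta pathway genes. Monocyte-like values with the strict filter went from -1.45 to 1.52 for Id1, from 1.77 to 1.30 for Id3, from -0.19 to -0.67 for cell cycle inhibitors and from 0.039 to 0.77 for S phase genes. Others went from -0.50 to 1.68 for G2/M genes, from -0.038 to -0.55 for p53 target genes, from 0.30 to -0.67 for mesenchymal transition genes and from 0.14 to -0.48 for inflammatory NF-kB genes. Others went from -0.25 to -0.69 for MHC genes, from 0.052 to -0.52 for immediate-early and heat shock genes, from 0.18 to 0.34 for oxidative phosphorylation genes and from 0.048 to -0.29 for scavenging and lysosome genes. Percents of cells with the strict filter went from 66.5 to 55.3 for percent of cells haematopoietic progenitor-like, control type H gate, from 66.3 to 50.03 for percent of cells haematopoietic progenitor-like, knockout type H gate, from 46.1 to 37.4 for granulocyte precursor-like in the labelled knockout sinusoidal and from 10.7 to 21.7 for monocyte-like in the labelled knockout sinusoidal. With the strict filter, sinusoidal over type H values in the control went from -0.71 to -0.52 for MHC genes.

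Progenitor-like values with the unnamed progenitor clusters added went from 0.31 to -0.15 for G2/M genes and from 0.0092 to -0.036 for MHC genes. Percents of cells with the unnamed progenitor clusters added went from 66.5 to 79.2 for percent of cells haematopoietic progenitor-like, control type H gate and from 66.3 to 84.6 for progenitor-like in the labelled knockout type H.

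Granulocyte precursor-like values without mitochondrial and ribosomal genes went from 0.16 to 0.22 for oxidative phosphorylation genes. Without mitochondrial and ribosomal genes, sinusoidal over type H values in the control went from 1.02 to 0.85 for S phase genes, from 0.60 to 0.44 for G2/M genes, from -0.44 to -0.61 for interferon response genes and from -0.71 to -0.87 for MHC genes median log2 sinusoidal gate over type H gate, control. Without mitochondrial and ribosomal genes, sinusoidal over type H values in the labelled knockout went from 1.63 to 1.51 for S phase genes and from -1.72 to -1.84 for MHC genes.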

Other observations

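Of the tests in this part, those of the missing endothelial cells and of Id3 were chosen after the result had been seen, as was the count of named genes near the targeted loci, while the other tests of those genes were chosen before it.

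Monocyte-like cells, a class chosen after the data had been seen, also differed in genes outside the interferon list, by the same rule of size. Higher in the library labelled knockout were Slc7a11, a cystine transporter, with a ratio of 3.73 (2.28 to 6.20), Gclm, of glutathione synthesis, with 4.81 (2.63 to 9.14), the chemokine gene Ccl2 with 2.43 (1.87 to 3.15), and Chil3 with 1.91 (1.82 to 2.01). Ccl7 had 0 UMIs in the control and stood at 58.7 CPM, from 20 UMIs, in the library labelled knockout. This was at least 15.1-fold higher against a floor of 3 counts in the control, or 11.2-fold by the exact interval. Gclm rested on 36 UMIs in the library labelled knockout and 17 in the control. Lower were Pglyrp1, with a ratio of 0.332 (0.238 to 0.453), and Serinc3, with 0.365 (0.280 to 0.470). Hmox1, of haem breakdown, had a ratio of 3.89 (2.91 to 5.23), but its log2 ratio was -0.23 in cluster 9 alone, the main control cluster, where that of Gclm was 1.02 in place of 2.24. Over all cells of the gate the log2 ratios of Slc7a11, Ccl2 and Chil3 turned to -0.48, -0.98 and -0.53, and that of Gclm lay at 0.13.

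No endothelial cluster was found in either gate, although the cells were sorted with endothelial antibodies. That 96.0% of cells held UMIs of at least 2 pan-haematopoietic genes does not settle low depth, since these are abundant transcripts and free RNA adds to them. Cdh5 was seen in 36.8% of cluster 11, at a median of 4540.5 UMIs. The deepest library, the sinusoidal labelled knockout with a median of 15428 UMIs, held 0 of 553 cells with UMIs of at least 2 of the 6 endothelial genes. The value in cluster 11 shows that Cdh5 can be seen at such depth, and argues against low depth as the whole cause for that gene. The deepest library decides little, since much of its depth lies in blood cell clusters 6 and 8, with medians of 16873 and 16731 UMIs. Its other endothelial genes are thus left open. In the type H gate the cells may be blood progenitors that carry endomucin, since Emcn was 22.5-fold (10.2 to 61.8) higher there than in the sinusoidal gate of the control, where it stood at 1.89 CPM. This leaves VE-cadherin unexplained, as Cdh5 gave 0 UMIs in clusters 0 to 4, rich in progenitors, and 42 of its 45 UMIs in dendritic cell-like cluster 11, and it leaves the sinusoidal gate open. Loss of endothelium before capture was not measured.

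Id3 is higher in the libraries labelled knockout, the opposite of what a loss of Id3 transcripts would give. Another mix of cell types is argued against by ratios standardised over clusters, which were 2.58 (2.16 to 3.07) in the type H and 1.86 (1.38 to 2.49) in the sinusoidal gate. A candidate explanation for a part of the difference is that animals of unlike Id3 genotype were pooled in the libraries labelled control, where Id3 in Xist cells over Y cells was 0.112 (0.0357 to 0.268) in the type H gate, but low Id3 in Xist cells as the whole cause is argued against by ratios within Y cells of 2.42 (1.87 to 3.15) in progenitor-like and 4.10 (2.71 to 6.25) in monocyte-like cells, while 1.51 (0.936 to 2.54) in granulocyte precursor-like cells leaves this open. Exchanged labels are not settled by Id3 at 38.8 CPM in the Y cells of the type H control, which could come from either labelling. The place of the tags on the null allele is not known. The pooling candidate needs a null allele with few tags, since Xist cells of the libraries labelled control held 4.34 and 6.39 CPM. With such an allele, the 74.4 to 94.7 CPM in Xist and Y cells of the libraries labelled knockout would argue against a loss of Id3 there. A difference by sex stays open too, as untested, although the libraries labelled knockout had ratios of 0.949 and 1.27.

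Genes named in the comparisons lie near the targeted loci: Serinc3 at 10.9 Mb and Cebpb at 15 Mb from Id1, and Ncmap at 0.745 Mb from Id3. These are 3 of 47 named genes within 20 Mb, where the 5.16% of all genes at that level would give 2.42, so the pooled number itself needs no explanation. By comparison they were 2 of 12 against 0.673 by share in progenitor-like cells, 1 of 13 against 0.758 in granulocyte precursor-like cells and 1 of 23 against 1.23 in monocyte-like cells. Serinc3 was lower in progenitor-like, granulocyte precursor-like and monocyte-like cells, and another mix of cell types is argued against by its standardised ratio of 0.526 (0.502 to 0.551) in the type H gate. Variants of another strain carried along with the loci, a hypothesis set beforehand, stay open, with the median absolute log2 ratio of other genes within 20 Mb at the 78.7 percentile of matched lists in the type H and at the 8.12 percentile in the sinusoidal gate. The bound written beforehand for that test decides nothing, because the named genes were left out of it and a variant in a single gene would not move a median.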
